A study of Homo sapiens with 3 samples.

How the data were processed

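RNA-seq was analysed for 3 samples of CD31+CD34+ cells derived from the H1 human embryonic stem cell line and sorted by surface CD105 as negative, low or high, with 1 library in each group. Per the labels' protocols, the cells were cultured for 2 days with activin A at 40 ng/ml and BMP4 at 50 ng/ml and for 3 days with VEGF at 40 ng/ml and bFGF at 50 ng/ml, and the samples carry day 4 as their time. Libraries were made from 2 ug of total RNA with a TruSeq RNA kit, which does not mark the strand of the transcript, and sequenced on an Illumina instrument, per the labels' protocols. The submitters' processing notes name BWA, Bowtie, RSEM and the build hg19, without a version, a role or an order. Filters and the gene annotation are not given in the sources used here. Reads of a gene and of an overlapping gene on the other strand cannot be told apart in such libraries.

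The deposited tables give 1 value per gene for 18345 genes in each library, with gene identifiers and symbols. Neither the labels nor the file headers name the unit. The deposited values were treated as FPKM, fragments scaled by transcript length and by the number of mapped fragments. They are not whole numbers, and the lowest values of genes with a single transcript fall on multiples of a fixed step once multiplied by transcript length. TPM would show such a step too, so the step speaks for values scaled by length and does not tell FPKM from TPM. That step was 0.0130, 0.0117 and 0.0125 FPKM times kilobases in CD105neg, CD105low and CD105high. Of the 248, 251 and 286 values tested, 54.8%, 58.6% and 51.4% lay within 0.04 half-steps of a multiple of a half-step, against a median of 4.84%, 5.98% and 5.25% for other steps. If the values are FPKM, the ratio of the steps gives a relative depth of 1.11 for CD105low and 1.04 for CD105high, with CD105neg set to 1. If the values were TPM, each library would differ by 1 constant factor. Centring removes that factor from the ratios, but not from the meaning of the pseudocount and of the floors, on which counts and fold changes of low genes depend. The name of the value column of the CD105neg library reads as CD105 positive, and the group was taken from the sample's own labels.

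Gene identifiers carry version numbers, and were matched, without the version, to GENCODE release 29 for transcript lengths and sequences (18317 genes matched). Because that annotation is on another build than the one in the submitters' processing notes, no coordinates are given. Shared sequence was measured by taking 50-base pieces every 40 bases from the annotated transcripts of each gene at or above 1 FPKM and counting the share that also occurs, on either strand, in a transcript of another gene. Values of genes with a large share are uncertain, since how reads were divided between genes is not given in the sources used here. At least 10% was shared for 2637 genes at or above 1 FPKM, of which 1361 were at or above 10 FPKM.

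The 3 pairs of libraries were compared by the log2 fold change of the value plus a pseudocount of 1, which understates the change of low genes. Genes at or above 10 FPKM in at least 1 of the 3 libraries were counted as higher or lower when at least 2-fold apart. With 1 library per group no p-value, standard error or number of significantly changed genes can be given, and none is. The order of the libraries was described by the share of genes 2-fold apart in a pair for which the remaining library lay in between, with exact (Clopper-Pearson) 95% intervals. The libraries were used on their deposited scale. The median log2 fold change over the counted genes was -0.10 for CD105high against CD105neg, 0.02 for CD105low against CD105neg and -0.11 for CD105high against CD105low.

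For 26 gene lists, members at or above 1 FPKM in at least 1 library were used and are called measured. They were counted as higher or lower when at least 1.5-fold apart. The median log2 fold change of each list was given as a percentile among 10000 random lists of the same size, matched on mean expression in 10 bins. This describes these libraries and is not a p-value. Medians below percentile 2.5 or above percentile 97.5 were called outside the central range. The lists named 532 different genes, of which 396 were analysed. Of the others, most are DNA-binding transcription factors and are not analysed here. The HOX list had no member and the list of blood transcription regulators 2, so neither was ranked.

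The genes named in the text were chosen by a fixed rule: ENG, PECAM1 and CD34; the 12 highest and 12 lowest log2 fold changes of CD105high against CD105neg and the 6 highest and 6 lowest of each other pair, among genes at or above 10 FPKM in 1 of the libraries compared, without clone-named, small RNA and mitochondrial genes; up to 4 members of each list with the largest absolute log2 fold change of CD105high against CD105neg; and 15 regulators and receptors whatever their values, of which 7 were analysed. The rule named 123 genes, some of which are not reported here. Groups, comparisons, lists, the naming rule, the settings and the first set of alternatives were fixed before the data were examined.

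The alternatives were a pseudocount of 0.1 or 5, centring on the median gene or on a mean trimmed by 30% at each end, no floor or a floor of 1 or 50 FPKM, a 1.5-fold or 4-fold threshold, list members at or above 10 FPKM, unmatched random lists, and list means in place of medians. Leaving out genes with at least 10% shared sequence and leaving out members held by another list were added after the data were seen. So was matching random lists on the length of the longest annotated transcript too. The steps were tested on simulated data. In simulated libraries of 18345 genes for CD105high against CD105neg, the 2-fold rule found 100% of 100 genes changed 4-fold and 45% of 100 genes changed 2-fold, and 0.0175% of 5714 unchanged genes passed it. In simulated libraries for CD105low against CD105neg, 5.5% of lists of 20 unshifted genes lay outside the central range. The spread in those simulations was assumed, the same at all levels of expression, and not measured between replicates. Changed genes were drawn only from genes with a mean of at least 20 FPKM, well above the floor of 10 FPKM, and unshifted lists from genes that vary independently. The shares therefore do not cover genes near the floor or lists of genes that vary together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.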

Results

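Gene expression was measured by RNA-seq in cells made from H1, an established human embryonic stem cell line. The samples are labelled as day 4 of differentiation, although the culture stages in the labels, of 2 and 3 days, add up to more. The cells, called HEPs in the labels, were sorted as CD31+CD34+ and then by their level of surface CD105 into a negative, a low and a high population, here CD105neg, CD105low and CD105high. CD105 is endoglin, a co-receptor for ligands of the TGF-beta and BMP family that endothelial cells carry. Each of the 3 populations had 1 library. There is no spread between replicates, so none of the differences below has a replicate check and each comparison is one of libraries. The deposited values, treated as FPKM, covered 18345 genes in each library. They summed to 289229 in CD105neg, 284824 in CD105low and 265618 in CD105high, and 5455, 5569 and 5298 genes reached 10 FPKM. The most abundant transcript was TMSB10 in all 3 libraries, at 2262, 2762 and 2993 FPKM, and the 10 most abundant genes together took 5.45%, 5.34% and 5.45% of the total. Judged from the spacing of the lowest values, and only if these are FPKM, CD105low was 1.11 times and CD105high 1.04 times as deep as CD105neg. The absolute number of reads is not given in the sources used here and was not derived from that spacing, so no counting interval is given for any value. Fold changes, and the 1.5-fold and 2-fold rules, refer to the value plus 1, which makes the fold of low genes smaller than the ratio of the printed values.

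ENG (ENSG00000106991.13), which encodes CD105, stood at 2.12 FPKM in CD105neg, 8.56 FPKM in CD105low and 13.8 FPKM in CD105high, which is the order of the sort. The other genes of the gate followed the same order. PECAM1 (ENSG00000261371.5), which encodes CD31, stood at 29.9, 41.9 and 50.1 FPKM, and CD34 (ENSG00000174059.16) at 21.0, 39.2 and 43.2 FPKM. Both were therefore present in all 3 populations, at lower levels in CD105neg. The value column of the CD105neg library carried a name that reads as CD105 positive, and ENG was lowest in that library.

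The comparison of CD105high with CD105neg spans the range of the sort. Genes of endothelial cells were higher in CD105high, and genes of the erythroid and megakaryocyte lineages were lower. With a pseudocount of 1, among genes at or above 10 FPKM in CD105high or CD105neg, without clone-named genes, the highest log2 fold change was that of LPL (ENSG00000175445.14), lipoprotein lipase, at 135 FPKM in CD105high and 5.81 FPKM in CD105neg (log2 fold change 4.32). FCN3, a ficolin that starts the lectin pathway of complement, followed with 314 against 17.7 FPKM (4.08), and ESM1, an endothelial proteoglycan, with 12.8 against 0.10 FPKM (3.65). The order of these genes depends on the pseudocount: with 0.1, ESM1 was above LPL (6.01 and 4.52), and with 5, FCN3 was above LPL (3.82 and 3.70). C8orf4 stood at 110 against 8.33 FPKM, OIT3 at 19.7 against 0.86 FPKM, and EDN1, the vasoconstrictor endothelin-1, at 23.5 against 1.69 FPKM. The basement membrane collagen gene COL15A1 (3.10), the GTPase gene GIMAP4 (2.84), the adhesion receptor gene ADGRF5 (2.79), BRINP1 (2.76), the heat-shock protein gene HSPA2 (2.75) and the endothelial receptor gene CD93 (2.70) completed the 12 highest. At the other end, HIST1H2AM, a histone H2A gene, stood at 45.2 FPKM in CD105high against 359 FPKM in CD105neg, and the embryonic globin gene HBE1 at 1.09 against 10.9 FPKM. Both values are uncertain, since 77.8% and 81.4% of the sampled sequence of these genes also occurs in other genes. FGFBP3, which encodes a protein that binds fibroblast growth factors, stood at 10.4 against 53.4 FPKM, BEX1 at 41.5 against 185 FPKM, MYL4, a myosin light chain of the embryo and the atria, at 1.83 against 10.9 FPKM, and RHAG, part of the Rh complex of red cells, at 5.71 against 26.3 FPKM. RIPOR3 (-1.99), the potassium channel gene KCNH2 (-1.98), the glycophorin gene GYPE (-1.85), NXF3 (-1.73) and the neuropeptide gene NTS (-1.67) were also among the 12 lowest, as was the read-through gene RPL36A-HNRNPH2 (-1.98), of which 92.6% of the sampled sequence is shared.

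Of 5919 genes at or above 10 FPKM in at least 1 library, 140 were at least 2-fold higher and 65 at least 2-fold lower in CD105high than in CD105neg. The median gene lay at a log2 fold change of -0.10. After centring on it, the split was 183 higher and 45 lower. With a pseudocount of 5 in place of 1, 32 genes were lower.

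**Figure D1:**
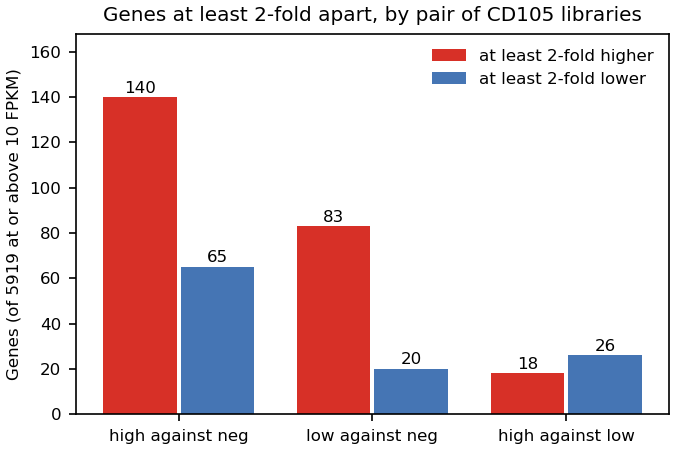
Number of genes, of the 5919 at or above 10 FPKM in at least 1 library, that were at least 2-fold higher (red) or lower (blue) in the first library of each pair, with the value + 1 before the ratio was taken. CD105high and CD105neg differed in the most genes (140 and 65), and CD105high and CD105low in fewest (18 and 26).

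Endothelial genes were mostly higher in CD105high. Of the 25 measured members of the pan-endothelial list, 17 were at least 1.5-fold higher than in CD105neg and 1 was at least 1.5-fold lower, and the median log2 fold change of the list, 0.86, lay above those of all 10000 expression-matched random lists. CDH5, the cadherin of endothelial junctions, stood at 94.1 against 48.0 FPKM, KDR, the main VEGF receptor, at 713 against 430 FPKM, and RAMP2, part of the adrenomedullin receptor, at 28.0 against 6.08 FPKM. The member that was lower was ICAM2, an endothelial and leukocyte adhesion molecule, at 17.2 against 50.9 FPKM; it was chosen after its values were seen. In the arterial and Notch list, 9 of 14 members were higher and 1 was lower, and the median of 0.76 lay above all random lists. The Notch ligand gene DLL4 stood at 18.5 against 4.18 FPKM, the gap junction gene GJA4 at 17.0 against 6.09 FPKM, NOTCH4 at 3.48 against 0.82 FPKM and NRP1 at 95.4 against 38.4 FPKM. In the venous and lymphatic list, 4 of 9 members were higher and none was lower (median 0.43, percentile 99.9), led by NT5E, EMCN and FLT4 with log2 fold changes of 1.67, 1.37 and 1.09. The 3 gate genes were all at least 1.5-fold higher (median 1.01, percentile 99.9).

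**Figure D2:**
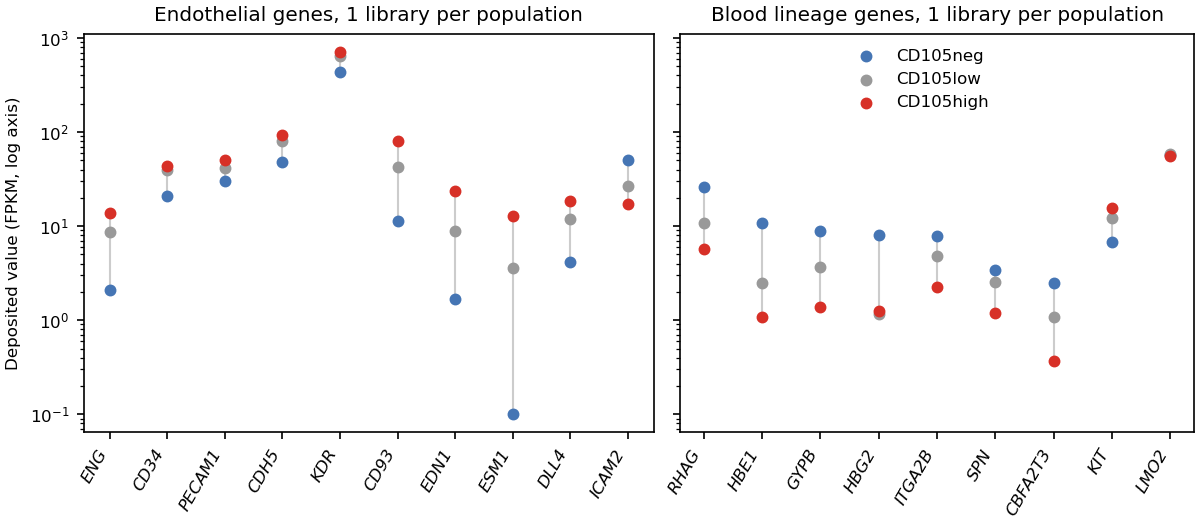
Deposited values in FPKM, on a log axis, of endothelial genes (left) and blood lineage genes (right) in the CD105neg (blue), CD105low (grey) and CD105high (red) library, with 1 point per library and no error. ENG goes from 2.12 to 13.8 FPKM from CD105neg to CD105high and RHAG from 26.3 to 5.71 FPKM, ICAM2 runs against the other endothelial genes, and LMO2 stays between 55.6 and 58.9 FPKM.

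Blood lineage genes were mostly lower in CD105high. Of the 26 members of the erythroid and megakaryocyte list with a value, 14 reached 1 FPKM in at least 1 library and were used. HBZ, HBA1, HBA2, SLC4A1 and AHSP were among those that did not. Of the 14, 12 were at least 1.5-fold lower than in CD105neg and none was higher, and the median of -1.20 lay below all random lists. Besides HBE1 and RHAG, the glycophorin gene GYPB stood at 1.38 against 8.92 FPKM and the fetal globin gene HBG2 at 1.27 against 8.10 FPKM, with 20.9% and 65.5% of their sampled sequence shared with other genes. In the list of blood cell surface genes, 13 of 22 members with a value reached 1 FPKM, and PTPRC did not. Of the 13, 7 were lower and 1 was higher (median -0.70, below all random lists). ITGA2B, the integrin chain CD41 of megakaryocytes and early blood progenitors, stood at 2.28 against 7.84 FPKM, SPN, which encodes the leukocyte sialoprotein CD43, at 1.19 against 3.42 FPKM, and the integrin gene ITGB3, which shares 56.4% of its sampled sequence, at 0.24 against 1.84 FPKM. The member that was higher was KIT, the receptor for stem cell factor, at 15.6 against 6.76 FPKM. Only 3 surface genes reached 10 FPKM, and their median of -0.17 did not stand apart (percentile 35.3). Of the transcription regulators of blood formation, 2 of the 25 fixed were analysed here. LMO2 stood at 55.6 against 57.4 FPKM, a difference whose sign changes on centring, and CBFA2T3 at 0.37 against 2.49 FPKM. RUNX1, GATA2, TAL1, GFI1, SPI1, SOX17, ID1, SMAD6 and the HOX genes were not analysed here.

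Among signalling lists, that of TGF-beta targets and receptors had 5 of 18 members higher and 2 lower (median 0.28, percentile 99.99). The collagen IV genes COL4A1 and COL4A2 stood at 273 against 118 FPKM and 231 against 111 FPKM, SKIL, a SMAD corepressor gene, at 42.7 against 17.8 FPKM, and COL1A1 at 8.57 against 21.4 FPKM. TGFBR2 stood at 13.1 against 7.89 FPKM. Of the 21 genes fixed for the BMP list, 9 were measured. The BMP target genes ID1, ID2, ID3, ID4, SMAD6, SMAD7 and SMAD9 were not analysed here, so the list does not cover them. In what remained of the BMP list, 3 of 9 members were higher and none was lower. The median of the list, 0.10, lay within the range of random lists (percentile 93.1). Among its members were the type II receptor gene BMPR2, at 12.1 against 4.60 FPKM, ACVRL1, which encodes the receptor ALK1 that works with endoglin, at 111 against 56.4 FPKM, and the BMP antagonist gene NOG, at 2.18 against 0.98 FPKM. BMP4 itself stood at 5.49 against 8.60 FPKM. In the VEGF response list, 2 of 12 members were higher and 2 lower (median 0.33, above all random lists), and this did not hold for its mean (0.19, percentile 97.4) or without members that other lists hold (0.12, percentile 94.6). The VEGF family gene PGF stood at 8.31 against 13.7 FPKM and the feedback inhibitor gene SPRY1 at 15.6 against 24.03 FPKM. In the interferon and inflammation list, 7 of 20 members were higher and none was lower (median 0.21, percentile 99.97). The interferon-induced genes IFIT1, IFIT2 and IFI44 stood at 36.7 against 8.57 FPKM, 3.17 against 0.58 FPKM and 3.64 against 0.70 FPKM, and SELE, the endothelial adhesion molecule E-selectin, at 93.1 against 30.1 FPKM.

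Ribosomal protein genes were lower in CD105high, with 9 of 25 at least 1.5-fold lower and none higher (median -0.56, below all random lists). RPS6 stood at 491 against 887 FPKM and RPS23 at 126 against 214 FPKM, with 12.4% and 15.5% of their sampled sequence shared with other genes. The cell cycle lists parted. In the DNA replication list, 6 of 24 genes were lower and none was higher (median -0.41, below all random lists), among them MCM2 at 26.5 against 45.7 FPKM and GINS2 at 7.43 against 14.2 FPKM. In the G2 and mitosis list, 1 of 25 genes was higher, BIRC5 at 31.6 against 17.3 FPKM, and none was lower. Its median of 0.11 lay at percentile 99.7, and its mean of 0.07 at percentile 94.4. The median of the G2 and mitosis list was larger for CD105low against CD105neg (0.25, percentile 99.99). For CD105high against CD105low it was -0.15 (percentile 13.9), so this list did not rise step by step with CD105. In the list of CDK inhibitors and p53 targets, 1 of 18 members was lower, CDKN1A at 67.0 against 119 FPKM, and none was higher (median -0.17, percentile 16.6). Respiratory chain genes were lower as a list (median -0.35, percentile 0.10), although 1 of 25, NDUFS1, was at least 1.5-fold lower and none was higher. In the glycolysis and hypoxia list, 3 of 24 genes were lower, ENO2, HK1 and ENO1, and none was higher. ENO2 stood at 21.6 against 60.4 FPKM, HK1 at 67.2 against 126 FPKM and ENO1 at 611 against 919 FPKM. The median of that list, -0.26, lay at the edge of the central range of random lists (percentile 2.51), and was outside it with a pseudocount of 0.1 (percentile 2.24), against unmatched random lists (1.42) and against lists matched on length as well (2.17). The list of immediate early and heat-shock genes that respond to dissociation had 1 of 11 members lower, ZFP36, and none higher (median 0.08, percentile 93.1). Against random lists matched on transcript length as well, a setting chosen after the data were seen, that median lay outside the central range (percentile 97.6). The housekeeping list had 2 of 25 members higher, among them B2M, and 1 lower, RPLP0 (median -0.13, percentile 42.5). In the histone list, 1 of 14 members was lower, HIST1H2AM, and none was higher; the median of -0.14 lay at percentile 55.8, and the mean of -0.36 at percentile 0.87.

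Markers of other cell types that the gate could hold were compared in the same way. In the pluripotency list, 1 of 10 members was lower, CDH1 at 0.82 against 1.80 FPKM, and none was higher (median -0.39, percentile 1.28). EPCAM stood at 3.44 against 5.46 FPKM. In the mesenchymal and mural list, 6 of 17 members were lower and 2 higher (median -0.19, percentile 19.1). PDGFRB stood at 2.74 against 9.05 FPKM and COL3A1 at 6.79 against 14.1 FPKM. None of the 3 measured mesoderm and cardiac genes, BMP4, MYL7 and PDGFRA, reached 1.5-fold on the value + 1 scale (median -0.56, percentile 1.15), and the list lay within the central range by its mean (-0.32, percentile 9.13) and with a pseudocount of 5 (-0.32, percentile 2.66). In the endoderm list, 2 of 5 members were higher, CER1 and APOB, and 2 lower, APOA1 and APOA2, all below 6 FPKM (median 0.12, percentile 87.1). None of the 3 measured neural genes reached 1.5-fold on that scale (median -0.32, percentile 16.2). Over the 24 lists, 8 medians lay above and 7 below the central 95% of random lists. The 8 include the gate genes, on which the cells were sorted, and lists share members, so the lists are not independent of the sort or of each other.

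**Figure D3:**
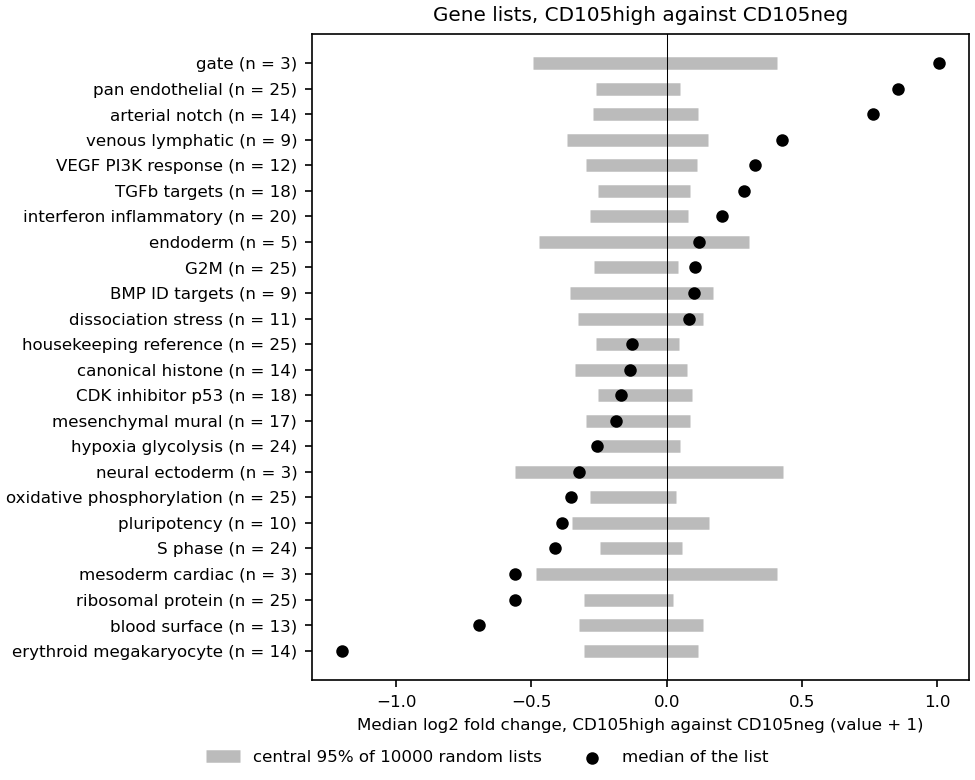
Median log2 fold change of CD105high against CD105neg (value + 1) of each fixed gene list, as black points, with the central 95% of the medians of 10000 random lists matched on expression as grey bars; n is the number of measured members. The pan-endothelial list (0.86) lies above its bar, and the erythroid and megakaryocyte list (-1.20) below it.

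Endothelial genes were also mostly higher, and erythroid and megakaryocyte genes mostly lower, in CD105low than in CD105neg. This comparison and that of CD105high use the same single CD105neg library, so a deviation of that library would move both alike. The endothelial list had 13 of 25 members at least 1.5-fold higher and 1 lower (median 0.70), and the arterial and Notch list 5 of 14 higher and none lower (median 0.48), both above all random lists. DLL4 stood at 11.98 FPKM in CD105low against 4.18 FPKM in CD105neg, and CD93 at 42.9 against 11.4 FPKM. The erythroid and megakaryocyte list had 9 of 14 members lower and none higher (median -0.66, below all random lists), with RHAG at 10.9 against 26.3 FPKM and HBE1 at 2.5 against 10.9 FPKM. The blood surface list had 5 of 13 members lower and 1 higher (median -0.31, percentile 0.03), but its 3 members at or above 10 FPKM did not stand apart (median -0.22, percentile 4.92). None of the 25 ribosomal protein genes was 1.5-fold apart, and the median of -0.27 lay below all random lists. Among genes at or above 10 FPKM in CD105low or CD105neg, without clone-named genes, the 6 with the highest log2 fold change were LPL (3.11), FCN3 (2.93), HSPA2 (2.76), the histone H4 gene HIST2H4A (2.75), C8orf4 (2.36) and B2M (2.13), which encodes the light chain of MHC class I. HIST2H4A shares 97.8% of its sampled sequence. The 6 lowest of the same genes were HBE1 (-1.76), PHLDA1 (-1.58), the kinase gene IRAK1 (-1.57), DSTN (-1.51), SENP3 (-1.51) and MYL4 (-1.46), and 52.6% of the sampled sequence of SENP3 is shared. Of the 5919 genes at or above 10 FPKM in any of the 3 libraries, 83 were at least 2-fold higher and 20 at least 2-fold lower. With a pseudocount of 5, 34 were higher and 10 lower. Without genes that share sequence, a setting chosen after the data were seen, 12 were lower.

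CD105high and CD105low were the most alike. The endothelial list had 5 of 25 members at least 1.5-fold higher in CD105high and 1 lower (median 0.24), and the arterial and Notch list 3 of 14 higher and none lower (median 0.34), both above all random lists. Those higher included ESM1 at 12.8 against 3.60 FPKM, EDN1 at 23.5 against 8.77 FPKM and DLL4 at 18.5 against 11.98 FPKM. The erythroid and megakaryocyte list had 6 of 14 members lower and none higher (median -0.35, below all random lists), and the blood surface list 3 of 13 lower and none higher (median -0.31, percentile 0.05), which turned to 0.06 over the 3 members at or above 10 FPKM. Among genes at or above 10 FPKM in CD105high or CD105low, without clone-named genes, the 6 highest were YPEL2 (1.65), ESM1 (1.59), RGCC (1.55), PHLDA1 (1.42), DSTN (1.34) and EDN1 (1.32). The 6 lowest of the same genes were HIST1H2AM (-3.08), the small GTPase genes RAP1B (-1.78) and RAB11A (-1.52), the translation elongation factor gene EEF1G (-1.67), GMFB (-1.67) and RPL36A-HNRNPH2 (-1.52). Of the sampled sequence of EEF1G, 97.6% is shared. Of the 5919 genes, 18 were at least 2-fold higher and 26 lower. The median gene lay at -0.11, and relative to it 22 genes were higher and 16 lower.

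CD105low lay between the other libraries for most genes that set them apart. Of the 205 genes at least 2-fold apart in CD105high and CD105neg, CD105low was in between for 192 (93.7%, exact 95% binomial interval 89.4 to 96.6%). The same share was 21.4% (22 of 103 genes, 13.9 to 30.5%) for CD105high between CD105low and CD105neg, and 54.5% (24 of 44 genes, 38.8 to 69.6%) for CD105neg between CD105high and CD105low. These intervals treat genes as independent, which they are not. Among the 140 genes higher in CD105high, the level in CD105low lay at a median of 71.3% of the way from CD105neg to CD105high on the log2 scale (interquartile range 64.6 to 77.4%). Among the 65 lower genes, the median was 52.8% (36.1 to 64.3%). CD105neg stood at least 2-fold apart from both other libraries for 83 genes, CD105high for 22 and CD105low for 9.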

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

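Leaving out genes that share sequence, matching random lists on length and leaving out members held by another list were chosen after the data were seen. No paired analysis was possible because each population has 1 library. For the same reason no library could be left out. Of 60 alternative counts of genes at least 2-fold apart, 24 stayed within 1.5 times the count reported. The others follow from the floor, the threshold or the pseudocount, except those under centring and without shared sequence. For CD105high against CD105neg (140 higher and 65 lower), the counts were 214 and 149 both with no floor and with a floor of 1 FPKM, 34 and 19 with a floor of 50 FPKM, 367 and 379 at 1.5-fold and 26 and 7 at 4-fold, and a pseudocount of 5 left 32 lower. For CD105low against CD105neg (83 and 20), they were 21 and 7 with a floor of 50 FPKM, 286 and 112 at 1.5-fold, 11 and 2 at 4-fold and 34 and 10 with a pseudocount of 5. The number lower was 41 with no floor or a floor of 1 FPKM and 12 without genes sharing sequence. For CD105high against CD105low (18 and 26), they were 31 and 43 with no floor or a floor of 1 FPKM, 6 and 9 with a floor of 50 FPKM, 74 and 131 at 1.5-fold, 1 and 1 at 4-fold and 11 and 11 with a pseudocount of 5. Centring on the median gene or the trimmed mean left 16 lower, which follows from the shift of the median gene. Of 18 alternative shares on the order of the libraries, 17 stayed within the interval of the share reported. The share of genes with CD105high between CD105low and CD105neg was 31.2% with a floor of 1 FPKM. With list members at or above 10 FPKM, 20 lists could be ranked, and 4 lay below the central range for CD105high against CD105neg and 3 for CD105high against CD105low. Of 489 alternatives for single lists, 458 stayed inside or outside the central range as reported, 18 moved inside it, 12 moved outside it, and 1 went from below it to the upper side of the random lists. That was the blood surface list for CD105high against CD105low, whose median was 0.055 over 3 members at or above 10 FPKM; the cause was not tested. The sign of the value itself changed in 9 of the 489, 3 of them for lists outside the central range as reported: this one and the VEGF response list for CD105high against CD105low, which went from a median of 0.003 to a mean of -0.03 and to a median of -0.02 without members held by another list. Of 588 alternatives for the fold changes of named genes, 541 stayed within 1.5-fold of the ratio reported and 47 did not, all under another pseudocount. With a pseudocount of 0.1, 132 stayed and 15 did not, and with 5, 115 stayed and 32 did not. Centring moves all genes of a pair alike, by at most 0.11 log2, so the alternatives under it could not cross 1.5-fold. ENG kept its order over the 3 libraries on centring, which so small a shift could not change.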

Other observations

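The tests of scale, dilution, globin balance, a single kind of blood cell, shared sequence and transcript number were chosen after the values they rest on were seen, as were the lists of liver sinusoidal and GIMAP genes.

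FCN3 and OIT3, among the genes highest in CD105high, are known from the sinusoidal endothelium of the liver, where FCN3 is also made by hepatocytes. The hypothesis that further genes of that endothelium go with CD105 was tested on the other members of a list of 20. Of these, 6 were measured at or above 1 FPKM, 3 of them were at least 1.5-fold higher in CD105high than in CD105neg and 0 were lower, and their median log2 fold change was 0.54 (percentile 99.9 among expression-matched random lists). CRHBP stood at 15.4, 39.6 and 53.0 FPKM in CD105neg, CD105low and CD105high, the mannose receptor gene MRC1 at 8.27, 14.9 and 17.7 FPKM and GPR182 at 0.25, 0.66 and 1.84 FPKM, whereas STAB1, F8 and CTSL were within 1.5-fold. STAB2, LYVE1 and CLEC4G, which also mark that endothelium, were at or below 0.11 FPKM in each library. The pan-endothelial list had a higher median of 0.86, so the result may reflect endothelial genes in general and does not single out a sinusoidal identity.

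GIMAP4 and GIMAP8, from a family of GTPase genes known from lymphocytes and endothelium, stood at 1.26, 9.53 and 15.2 FPKM and at 2.05, 9.25 and 15.7 FPKM in CD105neg, CD105low and CD105high. GIMAP8 was chosen after its values were seen. The hypothesis that the whole family goes with CD105 was tested on its other members. GIMAP5 and GIMAP6 were the 2 at or above 1 FPKM and had a median log2 fold change of 1.01 for CD105high against CD105neg. That median lay at percentile 99.5 among expression-matched random lists of 2 genes (upper end of their central range 0.63). With 2 genes the question stays open. GIMAP1, GIMAP2 and GIMAP7 were below 1 FPKM in each library.

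Endothelial genes were lower and blood lineage genes higher in CD105neg than in CD105high. Dilution of endothelial transcripts by other cells would lower them by a common factor. Their log2 fold changes ran from -1.51 to 3.65 over 20 members at or above 10 FPKM. The SD was 1.16 (percentile 99.7 of random lists, upper end of their central 95% 0.97). Without ESM1, EDN1 and CD93, which were among the 12 highest genes, it was 0.79 over 17 members (upper end 0.95). Leaving out the highest members lowers the SD by itself, and random lists do not show what SD a common factor would give. These values therefore cannot decide the question, and dilution stays open. For haemoglobin-making erythroid cells, which the CD31+CD34+ gate should largely remove, the values go both ways and leave the question open: HBZ, HBA1 and HBA2 summed to 0.14 FPKM in CD105neg, 0.64% of the 22.3 FPKM of HBE1, HBG1 and HBG2, and AHSP, the alpha globin chaperone, was at 0.14 FPKM, whereas ALAS2, of erythroid haem synthesis, was at 1.02 FPKM in CD105neg and 0.02 FPKM in CD105high. Shared sequence makes the globin values uncertain (81.4% for HBE1, 47.6% for HBG1, 65.5% for HBG2, not measured for the alpha-like genes). A single kind of other blood cell in differing shares cannot be told apart from expression in the sorted cells themselves: it would place CD105low at 1 point between the other libraries. That point was taken on the linear scale, as the fraction of the way from CD105high to CD105neg. Of 12 lower members, 6 (50%) lay within 0.1 of their median point of 0.22, which is nearer to CD105high, with HBG2 at -0.02 and PF4 at 0.93.

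Ribosomal protein genes were lower in CD105high than in CD105neg. The scale of the libraries does not account for this, as the median log2 fold change of the list was -0.46 after centring on the median gene. Among random lists matched on expression and on the length of the longest annotated transcript, the median lay at percentile 0. That length need not be that of the transcripts the cells make, so an effect of short transcripts stays open. Reads shared with other genes were not tested for this list and stay open too. Of the sampled sequence, 12.4% is shared for RPS6, 15.5% for RPS23, 30.9% for RPL13A and 33.7% for RPL10A. A difference in the preparation of single libraries or a difference between the populations also stays open, and neither could be tested.

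CD105low stood at least 2-fold apart from both other libraries for 9 genes. It was higher for B2M, EEF1G, RAP1B and TMEM263 and lower for AC004922.1, AP002990.1, DSTN, ORMDL3 and PHLDA1; those not named by the rule were chosen after their values were seen. The number of annotated transcripts per gene had a mean of 8.89 against a median of 10.4 for random gene sets (percentile 24.9), within their spread, so a division of reads among isoforms stays open. Reads divided between genes that share sequence cannot be told apart from other sources: 5 of the 9 genes (55.6%) share at least 10% of their sampled sequence, against a median of 22.2% for random gene sets. That share equals the upper end of their central 95% (percentile 97.9, with ties split). EEF1G stood at 215, 504 and 157 FPKM in CD105neg, CD105low and CD105high where AP002990.1, of which 78.1% is shared, stood at 209, 4.02 and 179 FPKM. B2M and ORMDL3 share 0% of their sampled sequence, so no shared sequence was found for them. Only exact matches of sampled pieces to annotated transcripts were counted, so shared reads cannot be excluded for these genes either. B2M stood at 12.2, 57.0 and 21.1 FPKM in CD105neg, CD105low and CD105high.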
